A study of Homo sapiens with 6 samples.

How the data were processed

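RNA sequencing was performed on SK-MES-1 cells, a human line derived from a lung squamous cell carcinoma, after transient knockdown of KRT6A, and on control cells, per the labels. The labels name 6 libraries in 3 groups of 2. They call the control group NC and the 2 knockdown groups si1 and si2. The labels do not spell out these names or give the sequences of the knockdown reagents, and nothing in them says that replicates 1 and 2 came from separate cultures. If the replicates are technical, the p-values measure only the spread between these libraries.

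The deposited values are FPKM, fragments scaled by gene length in kilobases and by sequencing depth, computed by the authors and given for 58735 genes with gene length in bases. The genome build was hg38, per the submitters' processing notes. The aligner, the counting program and the annotation were not given in the sources used here. All 58735 genes had the same start and end as in GENCODE release 29, whose coordinates are given in the text. Deposited FPKM multiplied by gene length was a whole multiple of 1 step in each library, within 0.001 reads, for 100% of the values. Dividing by that step recovered the reads behind each value, 14948607 to 17401392 per library. The denominator in the deposited FPKM was 1.0061 to 1.0184 times the sum of the recovered reads. For a gene with 0 reads, 3 reads were taken as the upper limit, which covers counting error only.

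The comparisons, tests, gene lists and alternatives were chosen before the data were examined, except where the text says otherwise. Values were tested as log2(FPKM + 1), so fold changes are on that scale and understate the change of genes with low values. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 12319 in all. limma 3.58.1 in R 4.3.3 was fitted to all 6 libraries with 1 coefficient per group, which left 3 residual degrees of freedom. Moderated variances followed a trend with the mean level, with 4.03 prior degrees of freedom. The 4 contrasts were the mean of si1 and si2 against NC, si1 against NC, si2 against NC, and si2 against si1. Tests were two-sided. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in its contrast. Errors in the text are the SD of 2 libraries for FPKM and limma's standard error (SE) for log2 fold changes.

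The text names KRT6A, RAB39B and 6 related keratins in any case. For the 2 knockdown groups together it names the 10 highest and the 10 lowest log2 fold changes among changed genes whose 4 knockdown libraries all lay on the same side of both NC libraries. Clone names, pseudogenes and non-coding RNAs were left out. The 3 highest and 3 lowest were named by the same rule for each other contrast. From each gene list the rule allows the 4 members with the largest change in the 2 groups together, and 6 for core autophagy. Some genes that the rule selects are not reported here. The exceptions are the highest members of the lists for other cell types and any gene said in the text to have been chosen after its values were seen.

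The 27 gene lists were tested with camera from limma at a preset correlation of 0.01, where at least 2 members were tested, and Benjamini-Hochberg adjusted over the lists of a contrast. This left 24 lists. camera was repeated with a correlation estimated from the residuals (statmod 1.5.0 was installed for limma), and fry was run on the same lists. Counts adjusted over the list alone used limma's p-values of the list's members only, and where the text gives no such counts they equalled those over all genes. The overlap between si1 and si2 was compared with 100 simulations of unchanged groups that shared 2 simulated control libraries, and with the overlap of independent lists.

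Each 7-base sequence was tested across genes for a difference in log2 fold change between genes that carry it in a 3' UTR and those that do not, adjusted for UTR length and GC content. At least 50 carriers were required, and p-values were Bonferroni adjusted over all sequences tested. The annotation gave a 3' UTR for 10499 of the 10762 protein-coding genes tested. The result is used to say which of the named genes carry the sequence with the lowest p among those lower in si1 or in si2, and to weigh the differences and the direction shared between si1 and si2.

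The fit and the list tests were tested on simulated reads with 1 dispersion for all genes and groups, estimated from the replicates. With 200 genes changed in both groups, the contrast of both groups with NC recovered 56.1% of genes changed 1.5-fold, 96.9% of those changed 2-fold and 98.2% of those changed 4-fold. These were 37, 63 and 56 genes, and 18 of 12116 unchanged genes were called. In si1 against NC, 37.9%, 92.3% and 98.2% (25, 60 and 56 genes) were recovered, with 12 unchanged genes called. In si2 against NC, 36.4%, 92.3% and 98.2% (24, 60 and 56 genes) were recovered, with 11 unchanged genes called. In si2 against si1, 39.7%, 91% and 100% (25, 61 and 60 genes) were recovered, with 15 of 12145 unchanged genes called. In each contrast, unchanged genes thus made up a larger share of the called genes than the threshold of 0.05 aims for. A planted list of 30 genes changed 1.5-fold had an adjusted p of 3.52e-61 with camera. In a separate simulation with no gene changed, 0 of 24 lists were called. Genes were simulated independently of each other, so this could not test list calls among correlated genes. With 1 dispersion throughout, the simulations also could not test how the fit handles spread that differs between genes or groups. In the sequence test, a planted shift of −0.2 was ranked 1 and recovered as −0.208.

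Alternatives were another pseudocount, no filter and a stricter filter on low values, median centring, quantile normalization, robust variance moderation, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. A voom fit to the recovered reads and a filter of at least 10 recovered reads were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the sequence tests and figures.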

Results

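Gene expression was measured by RNA sequencing in SK-MES-1 cells in 6 libraries: 2 of the control group NC and 2 each of the KRT6A knockdown groups si1 and si2. The 2 NC libraries held 16607606 and 17401392 recovered reads, the 2 si1 libraries 16054729 and 16653722, and the 2 si2 libraries 15700286 and 14948607. Between 12333 and 12439 genes reached 1 FPKM in each library. Mitochondrially encoded genes took 7.82% to 8.731% of the reads, and the 10 most abundant genes took 9.736% to 10.38%. Correlations across genes were 0.983 to 0.987 between libraries of the same group and 0.947 to 0.967 between libraries of different groups. Genes are not independent replicates, so these correlations carry no p-value. The first principal component took 47.2% of the variance and separated si1 from si2, with NC between them. The second took 28.1% and separated NC from both.

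KRT6A (ENSG00000205420, chr12:52487174-52493257, hg38), the gene targeted by the knockdown, encodes a keratin of stratified epithelia. It had 0 reads in each of the 6 libraries, the 2 NC libraries included. A count of 0 allows up to 0.0613 and 0.0583 FPKM in the NC libraries, 0.0627 and 0.0605 in the si1 libraries, and 0.0649 and 0.0678 in the si2 libraries. A fold change of KRT6A could not be computed, and a knockdown could not be detected, since the NC libraries held no KRT6A reads either. The labels of the libraries could not be checked from the targeted gene. KRT6C (chr12:52468516-52473785) also had 0 reads in all libraries, and KRT6B (chr12:52446651-52452126) had 1 read, in NC replicate 2, or 0.025 FPKM.

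Of the 6 keratins in the list for simple epithelia, 4 were abundant, while KRT20 (mean 0.00514 FPKM) and KRT23 (0 FPKM), both named after their values were seen, were not. KRT7 was at 180 ± 6.33 FPKM in NC (SD, n = 2), 145 ± 4.98 in si1 and 112 ± 1.04 in si2, and it fell by 0.50 log2 units in the 2 knockdown groups together (SE 0.0473, adjusted p = 0.00104). KRT19 averaged 91.0 FPKM in NC, KRT18 47.4 and KRT8 44.5. Of the 15 other keratins in the list for stratified epithelia, 3 reached a mean of 1 FPKM: KRT80 at 37.7, KRT10 at 17.7 and KRT15 at 1.28. KRT80 fell by 0.66 log2 units (SE 0.0715, adjusted p = 0.00158). KRT5, KRT14, KRT16 and KRT17, which pair with or resemble KRT6A, stayed below 0.4 FPKM in each library. Across the table, 8 of 55 keratin genes reached a mean of 1 FPKM. Of the cornified envelope and keratinocyte differentiation genes, 1 of 30 was tested, CSTA, at a mean of 1.34 FPKM, and 0 rose and 0 fell, or 0 and 1 adjusted over the list alone.

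**Figure D1:**
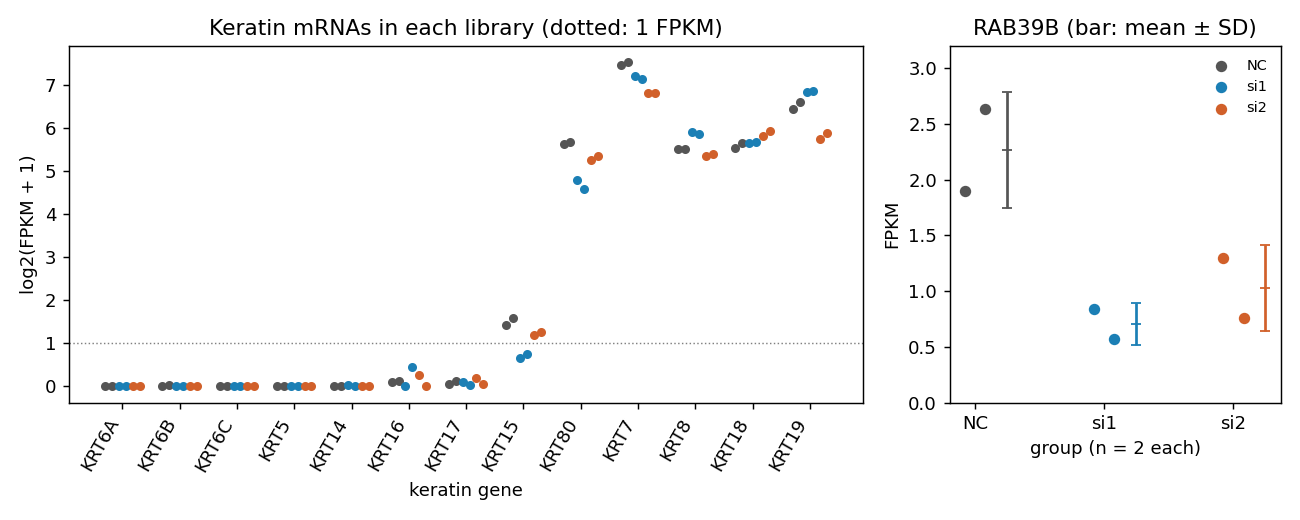
Left, log2(FPKM + 1) of keratins in each library, 1 point per library, with a dotted line at 1 FPKM; right, FPKM of RAB39B in each library with the mean and SD of each group (n = 2). KRT6A lies at 0 in all 6 libraries, and the means of RAB39B lie at 2.26 in NC, 0.705 in si1 and 1.03 in si2.

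RAB39B (ENSG00000155961, chrX:155258241-155264589, hg38), a Rab GTPase that the series title places between KRT6A and autophagy, fell in both knockdown groups. It was at 2.26 ± 0.521 FPKM in NC (SD, n = 2), 0.705 ± 0.187 in si1 and 1.03 ± 0.386 in si2. The log2 fold change was −0.81 for the 2 groups together (SE 0.174, adjusted p = 0.0191), −0.93 for si1 (SE 0.201, adjusted p = 0.0178) and −0.69 for si2 (SE 0.201, adjusted p = 0.0405). The 2 groups did not differ past the threshold (0.24, SE 0.201, adjusted p = 0.38). The values rested on 34 to 162 reads per library. The call for the 2 groups together was lost without NC replicate 1 (−0.97, adjusted p = 0.0629), without NC replicate 2 (−0.65, adjusted p = 0.159), without a filter on low values (adjusted p = 0.105) and in the fit that counted the spread between si1 and si2 as error (adjusted p = 0.143). Over all alternatives the log2 fold change ran from −1.42 to −0.65 and the adjusted p from 7.28e-05 to 0.159. The RAB39B call in si1 was lost without NC replicate 2 (adjusted p = 0.113), without si1 replicate 2 (adjusted p = 0.0804) and without the filter. The RAB39B call in si2 was kept in 7 of 15 alternatives, was lost in 5 of the 6 fits that left out a library, and had an adjusted p of 0.217 without NC replicate 2.

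The 3' UTR of RAB39B carries ACTCTCT, the sequence with the lowest p among those whose carriers were lower in si1. Of the other genes named in the text, ATG9A, CALM3, CLDN4, GINS1, KRT80, LAMP3, PXDN, RPL18, SLC35F3, SREBF2 and ZBED6CL carry it too. GTCTGCA, the sequence with the lowest p among those whose carriers were lower in si2, is carried by ATG2A, CEMIP, CLDN11, DHCR7, LAMP1, MCM4, OAS3, TMEM109 and UQCRQ. Over all 10499 genes searched, 980 carry ACTCTCT and 1098 carry GTCTGCA. Carrying a sequence does not by itself mark a gene as lowered, and ZBED6CL rose in si1.

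The comparison of the 2 knockdown groups together with NC asked which genes moved in the groups labelled as KRT6A knockdown. CPA4 (chr7:130293134-130324180), a secreted carboxypeptidase, showed the largest fall, from 8.09 ± 0.091 FPKM in NC to 0.688 ± 0.382 in si1 and 1.25 ± 0.227 in si2 (SD, n = 2; log2 fold change −2.23, SE 0.148, adjusted p = 3.25e-04). SLC35F3 (chr1:233904933-234324516), a solute carrier, fell from 18.6 ± 0.911 FPKM to 5.43 ± 0.399 and 4.66 ± 0.328 (−1.70, SE 0.075). AXL, a receptor tyrosine kinase, fell from 135 ± 0.406 FPKM to 35.8 ± 1.53 and 74.4 ± 2.37 (−1.37, SE 0.0509). ANKRD1, a nuclear cofactor and target of YAP, fell from 45.6 ± 0.0608 FPKM to 15.5 ± 3.44 and 19.8 ± 0.0334 (−1.34, SE 0.111). The other genes among the 10 lowest were MYEOV (−1.48), SERPINB2 (−1.43), PXDN (−1.41), CLDN11 (−1.36), CEMIP (−1.35) and TMEM109 (−1.31).

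AKR1B10 (chr7:134527592-134541408), an aldo-keto reductase, showed the largest rise, from 14.1 ± 0.614 FPKM in NC to 45.9 ± 2.92 in si1 and 35.5 ± 1.26 in si2 (SD, n = 2; log2 fold change 1.45, SE 0.0632, adjusted p = 1.39e-04). TPM4, an actin-binding tropomyosin, rose from 24.0 ± 1.46 FPKM to 55.3 ± 1.74 and 77.1 ± 0.0552 (1.41, SE 0.0564). CYP1B1, a cytochrome P450, rose from 49.1 ± 0.804 FPKM to 114 ± 6.66 and 136 ± 0.358 (1.32, SE 0.0518). Others among the 10 highest were CEBPD (1.44), OGFR (1.36), CXCL1 (1.24), TNFRSF11B (1.24), HABP4 (1.24) and GANAB (1.20).

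**Figure D2:**
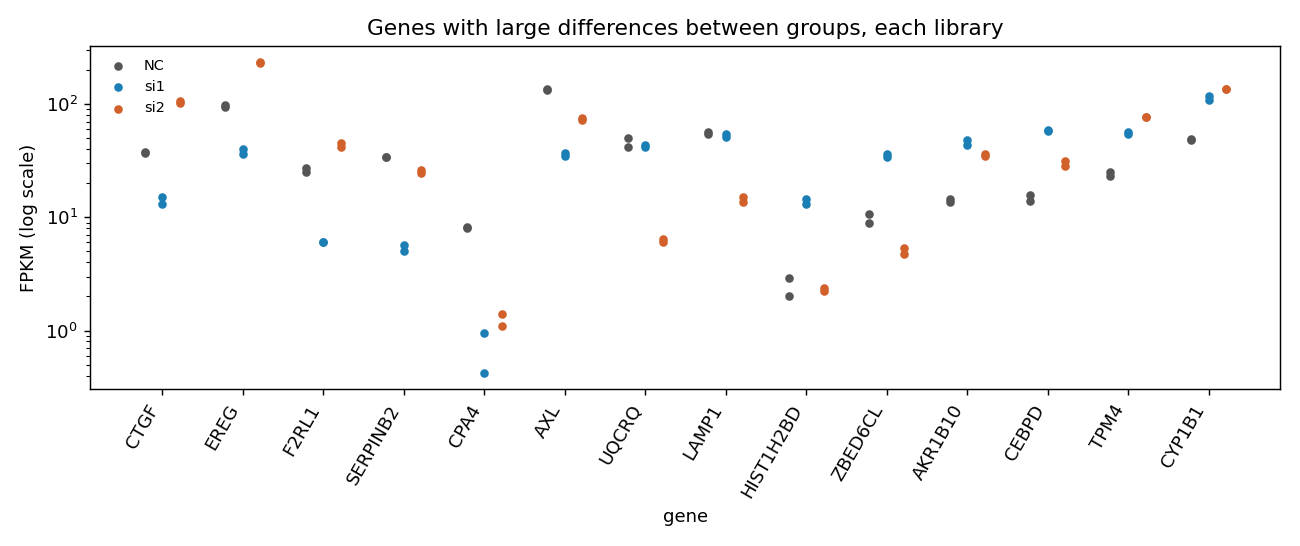
FPKM on a log axis of named genes in each library, 1 point per library, coloured by group. CPA4 fell from 8.09 in NC to 0.688 in si1 and 1.25 in si2, while AKR1B10 rose from 14.1 to 45.9 and 35.5.

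In all, 2529 of 12319 genes changed (20.5%), 1076 upwards and 1453 downwards. Of these, 37 rose and 52 fell by more than 2-fold. The count fell to 726 without NC replicate 1, to 701 without NC replicate 2 and to 1617 without si2 replicate 1. It was 84 in the fit that treated the 4 knockdown libraries as 1 group. In that fit CPA4, SLC35F3, ANKRD1, AKR1B10, TPM4, OGFR, CYP1B1, TNFRSF11B, HABP4 and GANAB stayed past the threshold, whereas AXL (adjusted p = 0.168), MYEOV, SERPINB2, PXDN, CLDN11, CEMIP, TMEM109, CEBPD and CXCL1 did not. Of the other genes given as changed in the 2 groups together, DDIT4, ELF3, IFIT2, LAMB3, PERP, RPS3 and SLC2A3 stayed past it.

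Among the fixed gene lists, the NRF2 targets rose as a group in the 2 knockdown groups together. NRF2 is a transcription factor that drives antioxidant genes, and of its 25 targets tested 11 rose and 4 fell, or 13 and 5 adjusted over the list alone (median log2 fold change 0.19). Besides AKR1B10, AKR1C1 rose by 0.79 (SE 0.0588), AKR1C2 by 0.82 (SE 0.0665) and ME1 by 0.87 (SE 0.067). The list's adjusted p was 5.53e-04, and its adjusted p = 0.339 with an estimated correlation. In si2 alone, 11 rose and 5 fell, and the list was not past the threshold (adjusted p = 0.149).

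The genes of cholesterol synthesis fell as a group, with 0 of 24 up and 16 down, or 0 and 17 adjusted over the list alone (median −0.35). HMGCS1, at the head of the pathway, went from 35.2 ± 0.764 FPKM in NC (SD, n = 2) to 24.4 ± 1.74 in si1 and 24.1 ± 1.42 in si2 (−0.52, SE 0.0662). MSMO1 fell by 0.54 log2 units (SE 0.0606), and SREBF2, a transcription factor of the pathway, by 0.55 (SE 0.0649). The list's adjusted p was 1.82e-05, and its adjusted p = 0.309 with an estimated correlation. In si1 alone this list was not past the threshold, with 3 up and 6 down, or 3 and 10 adjusted over the list alone (median −0.10, adjusted p = 0.254). The cytosolic ribosomal proteins fell too, with 0 of 44 up and 20 down, or 0 and 32 adjusted over the list alone (median −0.19). RPS3 went from 194 ± 7.27 FPKM to 123 ± 4.2 and 126 ± 0.923 (−0.63, SE 0.0476), and RPL18 fell by 0.51 (SE 0.0488). This list had an adjusted p of 4.86e-10, and an adjusted p = 0.521 with an estimated correlation. In si1 alone it was not past the threshold, with 0 up and 3 down, or 0 and 2 adjusted over the list alone (median −0.02, adjusted p = 0.537).

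Of 27 genes of the unfolded protein and integrated stress response, 2 rose and 12 fell, or 2 and 13 adjusted over the list alone (median −0.16, adjusted p = 5.53e-04, and adjusted p = 0.339 with an estimated correlation). CHAC1, a glutathione-degrading enzyme induced by ATF4, fell by 1.01 log2 units (SE 0.123), and SHMT2, a serine hydroxymethyltransferase of mitochondria, by 0.66 (SE 0.0551). DDIT4, a stress-induced inhibitor of mTORC1, rose by 0.75 (SE 0.0779). In si2 alone the stress response list was not past the threshold, with 7 up and 6 down, or 10 and 8 adjusted over the list alone (median 0.06, adjusted p = 0.751). Of 22 p53 targets, 2 rose and 7 fell, or 3 and 9 adjusted over the list alone (median −0.16, adjusted p = 0.0285, and adjusted p = 0.339 with an estimated correlation). AEN, an exonuclease in that list, fell by 0.57 (SE 0.0693). The p53 list passed in neither group alone (adjusted p = 0.106 in si1 and 0.443 in si2). The p53 call was lost without NC replicate 2 (adjusted p = 0.0675) and in the fit of the 4 knockdown libraries as 1 group (adjusted p = 0.25). With an estimated correlation none of the 24 lists passed, and fry called 9.

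The autophagy lists did not move as groups. Of 38 core autophagy genes, 5 rose and 4 fell, or 7 and 4 adjusted over the list alone (median 0.03, adjusted p = 0.751). ATG9A, a scramblase of autophagosome formation, went from 17 ± 0.626 FPKM in NC (SD, n = 2) to 10.7 ± 0.622 in si1 and 6.94 ± 0.937 in si2 (−0.90, SE 0.0851, adjusted p = 0.00102). Of 19 selective autophagy receptors, 1 rose and 1 fell, or 6 and 1 adjusted over the list alone (adjusted p = 0.353). Of 40 genes of the lysosome and its transcription factors, 8 rose and 9 fell, or 9 and 10 adjusted over the list alone (median −0.01, adjusted p = 0.896), and camera's direction for this list was up. LAMP1 (chr13:113297241-113323672), a lysosomal membrane protein, was at 55.4 ± 1.22 FPKM in NC, 52.7 ± 2.19 in si1 and 14.4 ± 1.03 in si2 (−0.97, SE 0.0619), and its 3' UTR carries GTCTGCA. CTSD, a lysosomal protease, rose by 0.49 (SE 0.0496). Of 17 genes in the list of RAB39B, its partners and Rab GTPases of the autophagy route, 0 rose and 2 fell, RAB39B and RAB1B (−0.73, SE 0.0538), and the list had an adjusted p = 0.868.

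Radiotherapy resistance, named in the series title, led to lists of DNA repair and cell cycle genes. Of 35 genes of DNA double-strand break repair, 0 rose and 3 fell, or 0 and 1 adjusted over the list alone (adjusted p = 0.353). Adjusted over all genes, 0 rose and 12 fell in si1, and 6 rose and 3 fell in si2. Of 30 genes of DNA replication, 1 rose and 8 fell (adjusted p = 0.282). The 2 groups moved apart here, with 0 up and 17 down in si1 and 11 up and 2 down in si2 over all genes. GINS1, a subunit of the replicative helicase, fell by 0.53 log2 units (SE 0.0695), MCM4 by 0.45 (SE 0.054) and TK1 by 0.48 (SE 0.0575). The fall of GINS1 was mostly that of si1 (−1.21 to −1.06 over the fits that left out a library). That of TK1 was mostly that of si2 (−0.82 to −0.71 over those fits). Of 29 mitosis genes, 2 rose and 2 fell (median −0.02, adjusted p = 0.969, with camera's direction up). Of 10 replication-dependent histones, 2 rose and 0 fell (adjusted p = 0.295). These moved apart too, with 6 up and 0 down in si1 and 0 up and 3 down in si2 over all genes.

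Genes of cell identity moved singly. Of 15 squamous and basal cell genes, 3 rose and 4 fell (adjusted p = 0.868). LAMB3, a chain of laminin-332, went from 211 ± 6.67 FPKM in NC (SD, n = 2) to 133 ± 10.3 in si1 and 139 ± 1.51 in si2 (−0.63, SE 0.0567), whereas PERP, a desmosomal protein, rose from 50.6 ± 1.76 to 96.5 ± 11.9 and 111 ± 0.651 (1.02, SE 0.0743). Of the 3 stratified keratins tested, 0 rose and 2 fell (adjusted p = 0.158). Of the 4 simple keratins, 0 rose and 1 fell, or 2 and 2 adjusted over the list alone (adjusted p = 0.868). Of 7 epithelial junction genes, 2 rose and 2 fell (adjusted p = 0.989). Their median was −0.08 while their mean was 0.03 and camera's direction was up. ELF3, an epithelial transcription factor, rose by 1.19 (SE 0.0782), and CLDN4, a claudin, fell by 0.83 (SE 0.109). Of 20 mesenchymal genes, 4 rose and 3 fell, or 4 and 4 adjusted over the list alone (adjusted p = 0.896). FN1, which encodes fibronectin, rose by 0.75 (SE 0.0857).

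Of 24 genes of NF-kB and inflammatory cytokines, 7 rose and 7 fell, or 7 and 9 adjusted over the list alone (adjusted p = 0.868). The chemokine genes CXCL1 and CXCL6 (0.83, SE 0.0757) rose, and the cytokine genes LIF (−0.82, SE 0.0637) and CSF2 (−0.79, SE 0.104) fell. The fall of CSF2 was mostly that of si1, at −1.70 to −1.37 against NC over the fits that left out a library. In those fits CSF2 was higher in si2 than in si1 by 1.335 to 1.665. Of 36 interferon-stimulated genes, 4 rose and 1 fell (adjusted p = 0.571). IFIT2 rose by 0.61 (SE 0.0597), and OAS3, an oligoadenylate synthetase, fell by 0.91 (SE 0.0998). Of 24 genes of hypoxia and glycolysis, 2 rose and 4 fell, or 2 and 7 adjusted over the list alone (adjusted p = 0.751), and the glucose transporter gene SLC2A3 rose by 0.76 (SE 0.0731). Of 13 mitochondrially encoded mRNAs, 1 rose and 1 fell (adjusted p = 0.571).

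**Figure D3:**
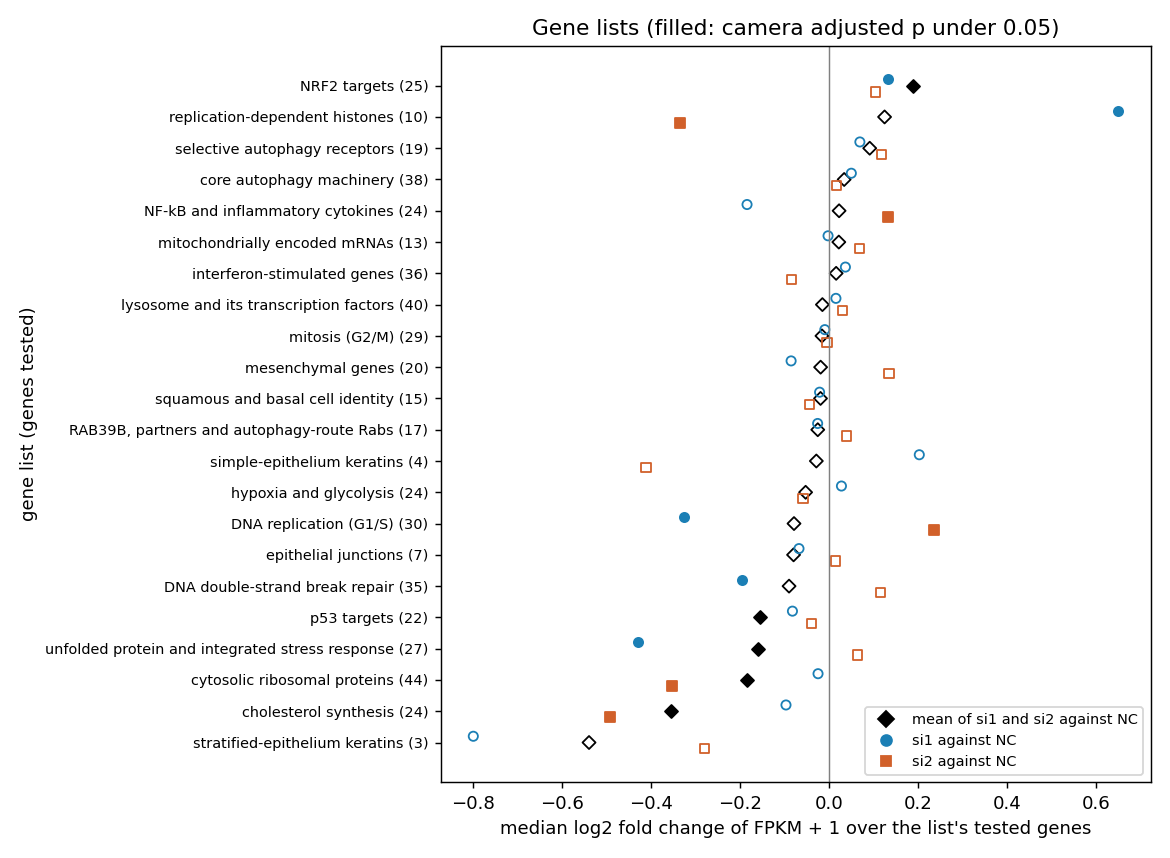
Median log2 fold change of FPKM + 1 over the tested members of each gene list, except those for other cell types, in si1, in si2 and in both together against NC, filled where camera's adjusted p with the preset correlation was under 0.05. Filled points for si2 lie at −0.49 for cholesterol synthesis and −0.35 for ribosomal proteins, and histones lie at 0.65 in si1 and −0.33 in si2.

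The comparison of si1 with NC asked what that group alone showed. SERPINB2 (chr18:63871692-63903890), a protease inhibitor, fell most, from 34.0 ± 0.0384 FPKM in NC (SD, n = 2) to 5.35 ± 0.488 in si1 (−2.46, SE 0.0781, adjusted p = 3.22e-05), followed by CPA4 (−2.45, SE 0.17) and CALM3 (−2.17, SE 0.111), 1 of 3 genes for calmodulin, whose 3' UTR carries ACTCTCT. HIST1H2BD, a histone H2B gene, rose most, from 2.46 ± 0.607 to 13.8 ± 1.13 FPKM (2.11, SE 0.131), followed by the transcription factor gene CEBPD (1.91, SE 0.0834) and ZBED6CL (1.75, SE 0.106). Of the 30 DNA replication genes, 0 rose and 17 fell, or 0 and 20 adjusted over the list alone (median −0.33, adjusted p = 1.81e-07, and adjusted p = 0.115 with an estimated correlation). GINS1, whose 3' UTR also carries ACTCTCT, went from 12.3 ± 0.997 to 5.08 ± 0.0718 FPKM (−1.13, SE 0.0803), and MCM4 fell by 0.54 (SE 0.0624). Of the 27 stress response genes, 2 rose and 20 fell, or 2 and 21 adjusted over the list alone (median −0.43, adjusted p = 1.28e-08, and adjusted p = 0.115 with an estimated correlation), among them CHAC1 (−1.26, SE 0.142) and SHMT2 (−1.14, SE 0.0636).

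Of the 35 double-strand break repair genes, 0 rose and 12 fell in si1, or 0 and 13 adjusted over the list alone (median −0.20, adjusted p = 3.30e-04, and adjusted p = 0.115 with an estimated correlation). The NRF2 targets rose (11 up and 2 down of 25, or 11 and 3 adjusted over the list alone, adjusted p = 1.08e-04, and adjusted p = 0.174 with an estimated correlation), with AKR1C1 up by 1.14 (SE 0.0679) and ME1 by 1.20 (SE 0.0773). The histones rose, with 6 of 10 up and 0 down, or 7 and 0 adjusted over the list alone (median 0.65, adjusted p = 7.73e-05, and adjusted p = 0.115 with an estimated correlation). MUC5AC, a marker of secretory cells, fell in si1 as well (−1.06, SE 0.198). fry called 12 lists. In all, 2758 genes changed, 1166 upwards and 1592 downwards, 70 and 141 of them by more than 2-fold. The count was 1114 without NC replicate 1 and 1257 without NC replicate 2.

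The comparison of si2 with NC asked the same of the other group. UQCRQ (chr5:132866560-132868031), a subunit of respiratory complex III, fell most, from 45.9 ± 5.98 FPKM in NC (SD, n = 2) to 6.28 ± 0.24 in si2 (−2.68, SE 0.0938, adjusted p = 3.18e-05), and was at 42.7 ± 0.862 FPKM in si1. TMEM109, a membrane protein, was also among the 3 lowest (−2.12, SE 0.0737). The 3' UTRs of UQCRQ and TMEM109 carry GTCTGCA, as does that of DHCR7, named below. IGFBP3, which binds insulin-like growth factors, rose most, from 33.7 ± 0.361 to 108 ± 2.57 FPKM (1.65, SE 0.0552), followed by CXCL1 (1.64, SE 0.0814) and TPM4 (1.64, SE 0.0651). Of the 44 ribosomal protein genes, 0 rose and 37 fell, or 0 and 39 adjusted over the list alone (median −0.35, adjusted p = 1.76e-15, and adjusted p = 0.468 with an estimated correlation), among them RPL34 (−0.80, SE 0.0668). Of the 24 cholesterol synthesis genes, 0 rose and 17 fell, or 1 and 20 adjusted over the list alone (median −0.49, adjusted p = 1.65e-08, and adjusted p = 0.161 with an estimated correlation). DHCR7, a sterol reductase of that pathway, went from 60.6 ± 0.928 to 28 ± 0.142 FPKM (−1.08, SE 0.0674).

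The DNA replication genes moved upwards in si2, with 11 of 30 up and 2 down, or 13 and 2 adjusted over the list alone (median 0.24, adjusted p = 0.0119, and adjusted p = 0.413 with an estimated correlation). The genes of NF-kB and inflammatory cytokines rose (9 up and 4 down of 24, median 0.13, adjusted p = 0.0455, and adjusted p = 0.413 with an estimated correlation), with CXCL6 up by 1.03 (SE 0.0874). The histones fell (0 up and 3 down of 10, median −0.33, adjusted p = 0.0434, and adjusted p = 0.413 with an estimated correlation). Of 18 alternatives, the NF-kB call was kept in 11 and the histone call in 9. Among the losses were 3 of the 6 fits that left out a library for NF-kB (adjusted p = 0.0796 without NC replicate 1) and 4 for the histones (adjusted p = 0.0827 without NC replicate 1). With a mean of at least 5 FPKM the adjusted p was 0.214 for NF-kB and 0.0539 for DNA replication, whose call was kept in 16 of 18, and the histone call was lost too. fry called 13 lists. Of the core autophagy genes, ATG9A (−1.19, SE 0.0983) and ATG2A (−1.09, SE 0.11), a lipid transfer protein whose 3' UTR carries GTCTGCA, fell. In all, 3578 genes changed, 1680 upwards and 1898 downwards, 76 and 154 of them by more than 2-fold. The count was 1665 without NC replicate 1, 1490 without NC replicate 2, 1686 without si2 replicate 1 and 1991 without si2 replicate 2.

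The direct comparison of si2 with si1 tested where the 2 knockdown groups differed, without the shared control. CTGF (chr6:131948176-131951373), a matricellular protein gene and YAP target, was at 37.2 ± 0.656 FPKM in NC (SD, n = 2), 14.2 ± 1.38 in si1 and 104 ± 2.4 in si2 (2.80, SE 0.0761, adjusted p = 8.88e-06). F2RL1, a protease-activated receptor, was at 26.4 ± 1.37, 6 ± 0.0114 and 43.4 ± 2.46 FPKM (2.66, SE 0.0731). EREG (chr4:74365143-74388751), a ligand of the EGF receptor, was at 96.2 ± 1.88, 38.3 ± 2.39 and 234 ± 5.13 FPKM (2.58, SE 0.0618). In the other direction, ZBED6CL differed by −2.60 (SE 0.106), UQCRQ by −2.59 (SE 0.0938) and HIST1H2BD by −2.16 (SE 0.131).

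Of the 24 lists, 8 differed between the 2 groups with the preset correlation, and none did with an estimated correlation. Higher in si2 were DNA replication (23 up and 1 down, adjusted p = 6.38e-09), the stress response (16 and 0, adjusted p = 1.42e-06), NF-kB and inflammatory cytokines (16 and 1, adjusted p = 1.19e-05) and double-strand break repair (18 and 1, adjusted p = 7.68e-05), each with an adjusted p = 0.0655 with an estimated correlation. Adjusted over the list alone, these counts were 27 and 1, 20 and 0, 18 and 1, and 21 and 1. GINS1 differed by 1.21 (SE 0.0803) and SHMT2 by 0.96 (SE 0.0636), and CSF2 was at 12.8 ± 2.22 FPKM in si1 and 37.9 ± 1.67 in si2 (SD, n = 2; adjusted p = 2.02e-04). Lower in si2 were ribosomal proteins (0 up and 34 down, adjusted p = 1.38e-10), histones (0 and 8, adjusted p = 1.38e-05), cholesterol synthesis (1 and 16, adjusted p = 3.63e-05) and NRF2 targets (4 and 16, adjusted p = 1.33e-03), or 0 and 35, 0 and 9, 1 and 17, and 4 and 16 adjusted over the list alone. With an estimated correlation, the ribosomal list had an adjusted p = 0.379, the NRF2 list an adjusted p = 0.204 and the histone and cholesterol lists an adjusted p = 0.0655 each. fry called 18. MUC5AC, the secretory marker, differed by 1.05 (SE 0.198). In all, 4743 genes differed, 2455 higher and 2288 lower in si2, 208 and 205 of them by more than 2-fold. The count was 2973 without si2 replicate 1.

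The agreement of the 2 groups asked how far they shared one response. Of the genes past the threshold in both comparisons with NC, 426 rose in both, 452 fell in both and 376 moved in opposite directions. Independent lists of these sizes would share 159, 245.3 and 396.8 genes. AKR1B10, TPM4 and CYP1B1 were among the genes that rose in both, CPA4, SLC35F3 and AXL among those that fell in both, and CTGF, EREG and F2RL1 among those that moved apart. Part of the excess over independent lists may come from the 2 NC libraries that both comparisons used, which cannot be split into separate controls of 2. The correlation of the log2 fold changes across genes was 0.287, and 57.3% of genes had the same sign. All 6 libraries were also simulated 100 times as unchanged, with each gene's fitted spread and 2 simulated controls shared by both comparisons. In these simulations the correlation averaged 0.503, from 0.451 to 0.560, and 66.7% of genes had the same sign. The covariance was 0.0394, against 0.01115 on average and 0.01337 at most in the simulations. The difference of 0.02825 estimates the part shared beyond the spread between control replicates. It still includes any difference common to both NC libraries, which the simulations did not hold. Genes are not independent replicates, so no p-value was computed for these measures.

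**Figure D4:**
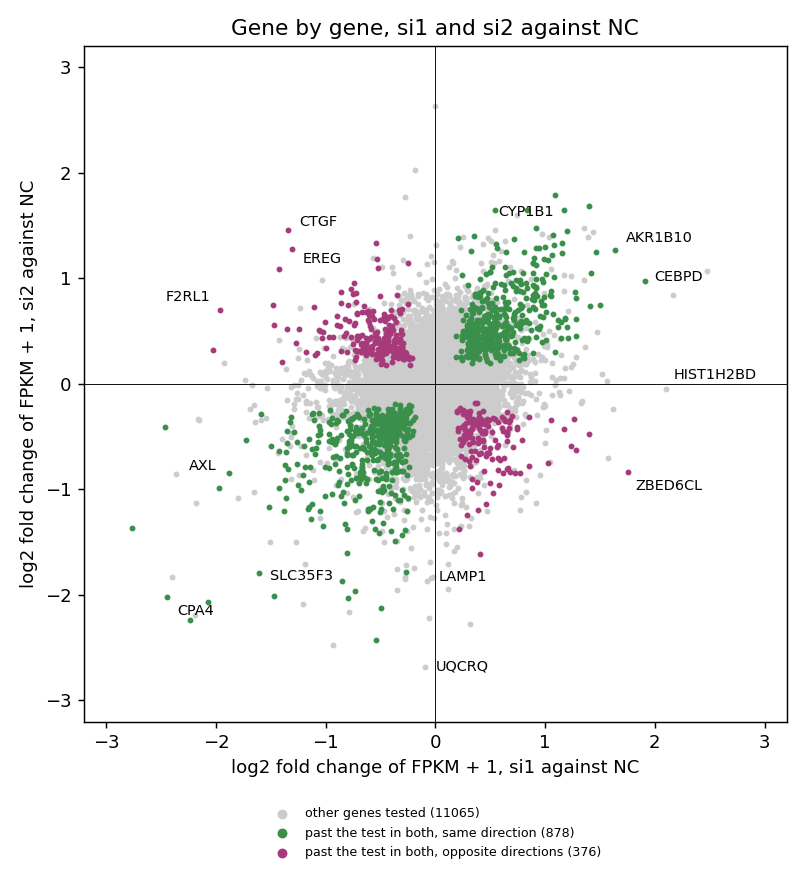
Log2 fold change of FPKM + 1 of each gene tested in si1 against NC (x axis) and in si2 against NC (y axis), coloured by whether it passed the test in both comparisons. 878 genes passed in both in the same direction and 376 in opposite directions, among them CTGF, EREG and F2RL1.

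Few markers of other cell types reached a mean of 1 FPKM. Of the fibroblast markers, 2 of 11 reached a mean of 1 FPKM, led by COL1A1 at 18.8, and of the 2 tested 1 rose and 0 fell (adjusted p = 0.349). The COL1A1 call was lost in 4 of the 6 fits that left out a library. Of the blood cell markers, 1 of 12 reached 1 FPKM, CD14 at 1.17. Of the endothelial markers, 0 of 8 did, with PECAM1 highest at 0.186. Of the lung alveolar and secretory markers, 2 of 14 did, led by MUC5AC at 15.4, and of the 2 tested 0 rose and 0 fell, or 0 and 1 adjusted over the list alone (adjusted p = 0.833). MUC5AC was at 18.9 ± 0.0508 FPKM in NC (SD, n = 2), 8.79 ± 3.26 in si1 and 18.7 ± 1.17 in si2. It fell in si1 (adjusted p = 0.0104), a call lost without NC replicate 1 (adjusted p = 0.0621), without NC replicate 2 (adjusted p = 0.059) and without the filter (adjusted p = 0.082). It was higher in si2 than in si1 (adjusted p = 0.00637), a call lost without the filter (adjusted p = 0.0559). Of the 2 genes in this list, 0 rose and 1 fell in si1 (median −0.61, adjusted p = 0.254), and 2 were higher in si2 than in si1 (median 0.74, adjusted p = 0.146).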

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

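The tests in this part were chosen before the results they weigh were seen, and each difference of a list or a single gene below was itself tested with camera or limma as si2 against si1. What singled these results out was a difference between the 2 knockdown groups, which the labels give the same target. Median log2 fold changes, si2 minus si1, were 0.575 for DNA replication, 0.454 for NF-kB and inflammatory cytokines, 0.355 for the unfolded protein and integrated stress response and 0.299 for DNA double-strand break repair. They were −1.05 for replication-dependent histones, −0.348 for cholesterol synthesis, −0.346 for NRF2 targets and −0.332 for cytosolic ribosomal proteins. None of these 8 lists passed with an estimated correlation, where the lowest adjusted p was 0.0655. Among single genes, CTGF differed by 2.80, F2RL1 by 2.66 and EREG by 2.58, and HIST1H2BD differed by −2.16, UQCRQ by −2.59 and ZBED6CL by −2.60. Of the genes past the threshold in both groups against NC, 376 moved in opposite directions, against 396.8 expected of independent lists, a count from the 2 separate comparisons that was not itself tested.

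If si1 and si2 are small interfering RNAs, which the labels do not say, matches of their first bases to 3' UTRs could lower genes in each group alone. In si1 the 980 genes carrying ACTCTCT were shifted by −0.123 (95% interval −0.146 to −0.100) and differed from si2 by 0.108, and in si2 the 1098 genes carrying GTCTGCA were shifted by −0.248 (95% interval −0.270 to −0.226) and differed from si1 by −0.237, each past the Bonferroni threshold. ACTCTCT and GTCTGCA both occur in transcripts of KRT6A, as do 10 of the 16 sequences lower in si1, 9 of the 18 lower in si2 and 14.6% of all tested. Many of those that passed overlap, however. Others that passed do not occur there, such as TATTTAT (−0.0644) in si1, and TGTCTGC (−0.2154) and AGTCTGC (−0.1744) in si2. TGTCTGC and AGTCTGC, like GTCTGCA, do occur in the reverse complement of KRT6A transcripts, whereas ACTCTCT and TATTTAT do not. The share of all tested sequences that occur in that reverse complement was not computed. GTCTGCA was carried by 48.4% of the 126 genes that fell 2-fold or more in si2, 5.6% of those that rose and 8.9% of those not past the threshold. For ACTCTCT in si1 the shares were 18.6% of 113, 4.6% and 8.4%. These shares were not tested, since the sequences were picked from the same fold changes. Of the 8625 genes with neither leading sequence 39.6% differed between si2 and si1, against 40.9% of all 10499. Genes with other forms of the sites and indirect effects remain among them, and genes with a site in a transcript not searched may too. The share of the difference that such matches account for therefore stays open. Scaling between libraries did not account for the difference, since 4708 genes differed after quantile normalization against 4743, and no biological explanation was tested, since KRT6A had no reads with which to compare the 2 knockdowns, and genes are not independent replicates in the sequence test.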

How the results depend on the processing

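The voom fit on recovered reads and the filter of at least 10 recovered reads were chosen after the results were seen; the other alternatives were planned. The counts of changed genes stayed within 1.5 times the values in the report, except as follows, in the order both groups against NC, si1 against NC, si2 against NC, and si2 against si1. Without a filter on low values, 1127, 1414, 1785 and 3130 genes changed, with 29572 genes adjusted over. Leaving out each library in turn gave 701 to 2844, 1114 to 2443, 1490 to 4047 and 2973 to 4367 genes, where the lone library of a group is assumed to vary like the other groups and fewer libraries enter the fit. Treating the 4 knockdown libraries as 1 group gave 84 genes for both groups against NC, since the spread between si1 and si2 then counts as error. RAB39B stayed at −0.81 but was not past the threshold without the filter or in that fit, and ran from −0.97 to −0.65 in the fits that left out a library, 2 of which lost the call, and reached −1.42 in the voom fit (adjusted p = 7.28e-05). Of the gene lists, 0 passed with an estimated correlation and 9 with fry for both groups against NC, against 5; for si1 and si2 singly 0 and 25 passed, against 10, and fry does not compare a list with other genes. The correlation of si1 and si2 effects stayed between 0.212 and 0.366.

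Reversals were confined to lists and genes not past the threshold, and list values are mean differences from other genes, whose sign can differ from that of camera or fry. Without a filter, the values were −0.015 for the lysosome list, −0.0085 for mitosis, 0.014 for epithelial junctions, 0.0049 for NF-kB, 0.014 for mitochondrially encoded mRNAs and −0.013 for lung alveolar markers. With a mean of at least 5 FPKM they were 0.015 for the RAB39B list, −0.42 for junctions and 0.0054 for NF-kB. fry gave −0.0018 for the lysosome list and 0.0057 for mitosis, and the fit of 1 knockdown group gave 0.0028 for mesenchymal genes. Median centring gave 0.050 for junctions and 0.0068 for KRT10, and quantile normalization gave 0.047 for junctions, −0.035 for mitochondrially encoded mRNAs and −0.075 for MT-ND3. For junctions, voom gave 0.029 and the filter of 10 reads 0.049. Leaving out 1 library gave −0.017 to 0.013 for the lysosome list, −0.090 to −0.043 for the RAB39B list, −0.013 to 0.025 for mitosis, 0.014 to 0.085 for junctions, −0.14 to 0.37 for CD14, −0.53 to 0.11 for HIST1H3H and −0.041 to 0.15 for LAMP3. The cause of these reversals was not tested.

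Of the other planned values, 5190 kept their direction and side of the threshold, 566 were no longer past it and 21 newly passed it. The planned edgeR and DESeq2 fits were not run, since the deposited values are FPKM, and voom stood in for them (3672, 3924, 4700 and 5732 genes of 15185). No pairing by replicate number was seen (correlations of deviations −0.052, 0.0503 and −0.0577), which cannot show whether libraries with the same number were prepared together. A block for the replicate number gave 2058, 2335, 3121 and 4314 genes. KRT6A gave no value under any alternative. The variance between libraries was 3.577 times that of counting alone in NC, 8.282 times in si1 and 3.518 times in si2, so over all genes counting error was not the main part of that variance.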

Other observations

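Of the tests in this part, the limit set by depth, the count of stratified keratins and the sequences shared by both groups were chosen only after the results were seen.

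The absence of KRT6A reads in all 6 libraries was weighed against 3 explanations. If reads shared with near-identical keratins had been dropped, little of KRT6A would be unique. However, 67.9% of the 50-base windows of its transcripts have no exact match in another gene, which argues against this as the whole cause of 0 reads. It does not exclude it, since windows that differ by a single base counted as unique and the aligner was not given. Depth could not have hidden a level of 1 FPKM, since 3 reads would have given 0.0678 FPKM in the shallowest library, but a level below that limit stays open. That these cultures did not express stratified keratins also stays open. Of the 15 other stratified keratins only 3 reached 1 FPKM, KRT80 at 37.7, KRT10 at 17.7 and KRT15 at 1.28. The highest of the rest, KRT16, averaged 0.121 FPKM. Low values of most members are what this explanation predicts, but it was drawn from the same values, which therefore cannot support it. It may also be that reads of KRT6A were removed before the table was made or that the libraries came from other cells, and neither was tested.

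The direction shared by si1 and si2 was weighed against 2 explanations. Spread between the replicates of the shared NC group did not account for all of it, since the covariance of 0.0394 lay above the highest of the simulations, 0.01337. The simulations held only such spread, as fitted over the 3 groups, so they could not exclude a difference common to both NC libraries. If NC is a control small interfering RNA, genes matching its first bases could be lower in NC and so appear higher in both knockdown groups. Carriers of 6 sequences of 7 bases were higher in both and of 0 lower in both, but the 6 all contain GGAGA and so are not separate findings, and the leading one, TCGGAGA with 185 carriers, was shifted by 0.175 in si1 and by 0.236 in si2. Since both comparisons use the same NC libraries, another difference of these that follows 3' UTR sequence could give the same result, so this explanation stays open, and a loss of KRT6A could not be set against it, since KRT6A had no reads in NC.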
